A study of Homo sapiens with 12 samples.

How the data were processed

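The study compared trimethylation of lysine 9 on histone H3 (H3K9me3) between wild-type (WT) 293T cells and 293T cells with a knockout (KO) of SMARCA3, the gene whose current symbol is HLTF. Per the labels' protocols, cells were fixed with formaldehyde, their chromatin was sheared by sonication, and fragments bound by an anti-H3K9me3 antibody were precipitated and sequenced beside input chromatin. The labels list 12 libraries, made of 3 ChIP and 3 input libraries per genotype, and call them biological triplicates. The submitters' processing notes name HISAT2 and the genome build hg38. The peak caller, its settings, the use of the input libraries in it and the way the 3 replicates were combined are not given in the sources used here.

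The files used here are 2 peak lists, 1 per genotype, in which the authors gave each region a position, a fold enrichment, a q-value and an annotation to a transcript. The column names do not define the fold or the q-value. The fold was read here as a ratio of ChIP signal over background at the peak. The q-value was read as an adjusted p of each peak within its own list. Both are the authors' values throughout, and they were used to describe, rank or filter peaks, never as a measurement with replicates. The lists hold no column per library, so the read depth of each library is unknown here, the spread between replicates could not be measured, and no p-value was computed between genotypes. The planned test of H3K9me3 per region between the 6 ChIP libraries was therefore not run. Intervals are Wilson 95% intervals for a share of peaks or genes, or the same interval turned into a ratio, or Newcombe's combination of 2 Wilson intervals for a difference of shares. They treat peaks as independent, also shared peaks that overlap between the lists, and cover counting only, not the variation between cultures. A sum of peak bases depends on how much of the genome was called in each list, so covered length and mean width are given beside the genome-wide ratio.

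Peak positions were read as counted from 1, because the lowest start in either list is 1. Peaks of a list were called shared where they met a peak of the other list by at least 1 bp on chromosomes 1 to 22, X and Y. The level of chance overlap came from 1000 random rotations of the KO peaks within each chromosome. Annotation classes are those of the authors' column, in which the promoter classes reach 3 kb to either side of a transcript start. Covered bases were summed per chromosome and in windows of 1 Mb on chromosomes 1 to 22 and X. Genes were taken from the authors' gene column, which names a gene only for peaks of the gene-body and promoter classes. Intergenic and subtelomeric peaks, 48.6% of WT and 48.9% of KO peaks, have no gene there and enter no count by assigned gene. A table of human RefSeq genes (assembly GRCh38.p14) gave gene lengths and bodies. It held 4964 of the 5036 protein-coding names in the lists, or 98.6%, and 6853 of all 9261 names, or 74.0%. Of 6602 names equal to a current symbol, 6578 had overlapping coordinates in both sources (99.6%), so its coordinates were used as hg38. The share of each of 16 gene lists with a peak was set beside 10000 random lists of as many protein-coding genes, drawn within 20 classes of gene length. Protein-coding genes were the background because noncoding names differ between annotations. The share of protein-coding genes with at least 1 peak was 20.7% in WT and 23.4% in KO.

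The genes and regions named were chosen by a rule written before the data were examined. It takes the targeted gene, the 10 genes with the most KO-only and the 10 with the most WT-only peaks, the genes of the 5 peaks of highest fold in each list, up to 4 members of each gene list with the largest difference in peak bases, and the 5 windows of 1 Mb with the largest gain and the 5 with the largest loss of covered bases. The gene lists and the alternatives in thresholds, overlap, peak units, list length and gene assignment were fixed at the same time, apart from those named below as chosen after seeing the data.

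Chosen after seeing the data were the stretches of windows, the segments, the background measure and some alternatives. A gained stretch is at least 3 adjacent windows that each hold at least 40 kb more peak bases in KO, and a lost stretch is at least 5 adjacent windows that each hold fewer peak bases in KO. Segments of constant KO share of all peaks were found by recursive splitting of each chromosome, where a split had to raise the log likelihood by at least 20 and leave at least 5 Mb on each side. The background measure rests on the fold values. In both lists many of them lie on an even grid, with a step of 0.0788 in WT and 0.0772 in KO (tolerance 1.5e-05), as they would if one constant background served for these peaks. This held for 56.4% of WT and 52.1% of KO peaks. The remaining values were read as peaks whose local background lay above the constant one, and the share on the grid served as a proxy for local input. That reading comes from the values and not from a stated method.

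The calculations were made in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. The steps were tested on simulated data. All 2995 planted overlaps among 5000 simulated peaks were found. In 50 simulated copies of chromosome 3, which used its 7025 real peak positions, 88 of 100 planted segment ends lay inside the interval given for them, with a median distance of 213 kb and 0 false ends, and 20 permutations of the peaks of all chromosomes gave 0 ends. These simulations and permutations gave each peak its list independently of its neighbours. They do not show how often false ends arise where peaks of a list cluster. Of 20 simulated lists of 100 genes with a raised share of peaks, 20 lay above percentile 97.5, and the median percentile of unchanged lists was 48.1. Peaks on unplaced, unlocalized or alternate sequences were left out of the overlap, chromosome, window and segment comparisons. They were counted among the peaks outside the gained and lost stretches, also among the shared peaks of the background measure. A test of 1 further gene list, added after seeing the data, is not reported here.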

Results

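H3K9me3, a histone mark of constitutive heterochromatin and silenced repeats, was profiled by ChIP-seq in 293T cells with and without SMARCA3. The 293T line derives from human embryonic kidney cells and carries the SV40 large T antigen. SMARCA3 (HLTF) is a SWI/SNF-related DNA translocase with a RING finger, the domain of ubiquitin ligases, and the series title presents it as a histone H3 ubiquitin ligase that regulates H3K9me3. The data were 2 peak lists, 1 for each genotype, in a series with 3 ChIP and 3 input libraries per genotype. How the libraries entered each list is not given. With 1 list per genotype no difference below has a replicate check, and the intervals cover the counting of peaks or genes only.

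The targeted gene carried no H3K9me3 peak in either list. HLTF lies on chromosome 3 from 149030063 to 149086533 (hg38), and no WT or KO peak fell inside it or was assigned to it. The nearest peak on the lower side was called in both lists, 4202 bp away in WT and 4441 bp away in KO, with a fold enrichment of 6.45 and 5.03. On the other side the next peak began 303261 bp away in WT and 365379 bp away in KO. A peak list does not measure expression, so these values do not check the knockout.

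The first comparison asked how much of the genome carried the mark in each genotype. The KO list was longer and its peaks were wider. It held 65170 peaks over 53.1 Mb, against 46898 peaks over 33.3 Mb in WT, a ratio of 1.39 for peaks (95% interval 1.37 to 1.41) and 1.59 for covered bases. Mean peak width was 814 bp in KO and 710 bp in WT, and 22.8% of KO peaks against 18.0% of WT peaks exceeded 1 kb. The widest peak on a chromosome spanned 62714 bp in KO, in an intergenic part of chromosome 19 from 24325488 to 24388201, and 22535 bp in WT, over the zinc finger gene ZNF678 on chromosome 1 from 227644102 to 227666636. The 5 peaks of highest fold in each list all lay outside genes. In WT they were 2 adjoining peaks on chromosome 20 (31057660 to 31069485), 2 on chromosome 10 (from 41853774 to 41891095) and 1 on chromosome 1 (125167911 to 125171196), with folds from 15.1 to 20.3. KO shared the pair on chromosome 20 and the stretch on chromosome 10, where its peak was 35699 bp wide, and added a peak on chromosome 5 (49656264 to 49662028) and 1 on an unplaced sequence, with folds up to 23.4. The lists were called with unequal sensitivity, since a peak of fold 3.53 in WT had a q-value of 4.0e-05 and one of fold 3.51 in KO had 5.9e-07. The ratio of peaks was 1.08 among peaks at or above the median fold of both lists, 3.69, and 1.54 (1.43 to 1.66) among peaks of fold 6 and above.

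**Figure D1:**
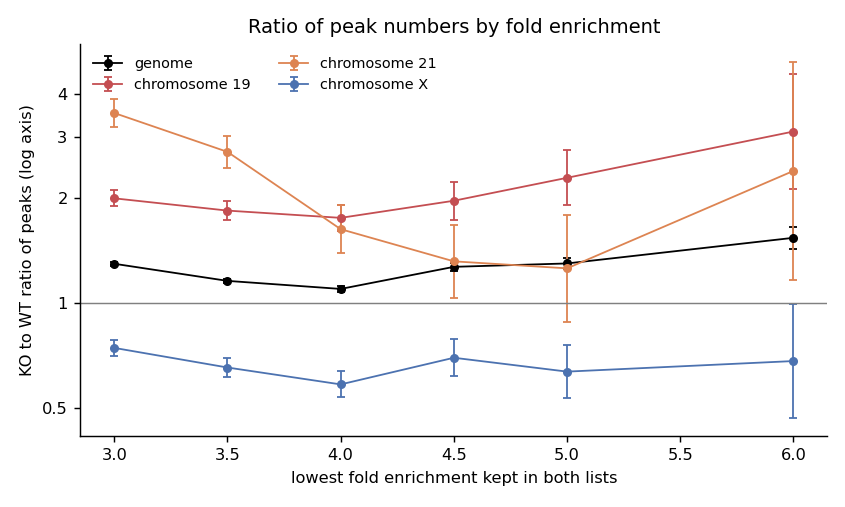
Ratio of KO to WT peaks (log axis) among peaks at or above each fold enrichment, for the genome and for chromosomes 19, 21 and X, with 95% counting intervals as bars. The genome ratio lies at 1.10 from fold 4 and 1.54 from fold 6, and chromosome X stays below 1 at every threshold shown.

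The second comparison asked whether KO cells were marked at the same places. Most WT peaks met a KO peak, and about as many KO peaks met no WT peak as met one. Of 46474 WT peaks on the chromosomes, 79.9% (79.6 to 80.3) met a KO peak, and of 64598 KO peaks, 50.6% (50.2 to 51.0) met a WT peak. Rotated KO peaks met a median of 3.35% of WT peaks. This left 31934 KO-only and 9319 WT-only peaks. Those of one genotype alone were narrow, with a median of 401 bp in KO and 349 bp in WT, beside 809 and 551 bp for shared peaks. Among the peaks in the top quartile of fold, 94.4% of WT and 81.6% of KO peaks were shared. When at least 50% of both peaks had to overlap, the shared shares were 40.5% in WT and 29.1% in KO. Counting peaks within 1 kb of a peak of the other list, they were 88.4% and 63.6%. Because the lists were called with unequal sensitivity, a KO-only or WT-only peak need not be a place unmarked in the other genotype.

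Promoters took a larger part of the KO peaks. The classes within 3 kb of a transcript start held 9.62% of KO peaks (9.40 to 9.85) and 8.16% of WT peaks (7.92 to 8.41), a difference of 1.46 percentage points (1.13 to 1.80). Promoter peaks numbered 6271 in KO and 3827 in WT, a ratio of 1.64, and the class closest to the transcript start, within 250 bp, had a ratio of 1.83 (595 and 325 peaks). Gene bodies had a ratio of 1.33 and intergenic regions 1.40. By type of the assigned gene, the ratio was 1.59 for lincRNA genes and 1.31 for protein-coding genes. In lists of 46898 peaks each the promoter difference was 0.716 percentage points.

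Along the chromosomes the gain was uneven, and parts of the genome had fewer KO peaks. Chromosome 21 had 2252 KO and 640 WT peaks, a ratio of 3.52 (3.22 to 3.84), and chromosome 19, which holds most clustered zinc finger genes, had 4789 and 2298, a ratio of 2.08 (1.98 to 2.19). Chromosomes 16 and 7 followed with 1.83 and 1.68. The excess on chromosome 21 lay in weaker peaks, with a ratio of 1.63 from fold 4, where the genome stood at 1.10, and 1.26 (0.883 to 1.80) from fold 5, where the genome stood at 1.301. From fold 6 it was 2.40 (1.17 to 4.94), with 10 WT and 24 KO peaks. Chromosome X was the only one of the 23 compared with fewer KO than WT peaks (2749 and 3467, ratio 0.793, 0.754 to 0.834), and chromosomes 13, 1 and 10 had the next lowest ratios, 1.16, 1.17 and 1.18. In covered bases the ratio was 3.09 on chromosome 21, 2.44 on chromosome 19 and 0.873 on chromosome X. An alternative chosen after seeing the data kept peaks at or below the median q of both lists. There the ratio of bases was 1.09 on chromosome X and 3.12 on chromosome 21. That cut admits weaker peaks in KO, where a like fold had a smaller q. On chromosome 13 the ratio of bases changed from 1.14 to 0.952 among peaks at or above the median fold.

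**Figure D2:**
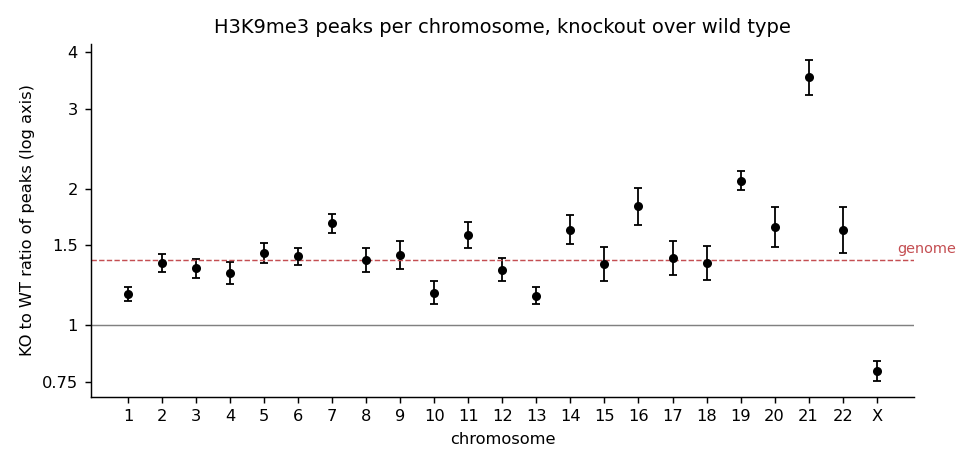
KO to WT ratio of H3K9me3 peaks on each chromosome (log axis), with 95% counting intervals as bars. The dashed line marks the genome-wide ratio of 1.39. Chromosome 21 lies highest at 3.52 and chromosome X lowest at 0.793.

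Of the 2828 windows of 1 Mb with peaks, 2522 had more covered bases in KO and 306, or 10.8%, had fewer. The window with the largest gain lay beside the centromere of chromosome 7, from 62 to 63 Mb, with 61940 bases in WT and 295863 in KO and no protein-coding gene in the annotation used. The other 4 were on chromosome 19 and filled with zinc finger genes. From 37 to 38 Mb, where 14 of 17 protein-coding genes are zinc finger genes, ZNF420, ZNF585A and ZFP30 among them, covered bases were 139799 in WT and 344631 in KO. From 22 to 23 Mb, with ZNF208, ZNF98 and ZNF99, WT had 25 peaks and KO had 341. The windows from 52 to 53 Mb (ZNF615, ZNF83) and 36 to 37 Mb (ZNF146, ZNF382) gained 175607 and 171312 bases. Losses were smaller. Of the 5 windows with the largest loss, 4 lay in gene-poor parts of chromosome 13, at 81 to 82 Mb (91151 bases in WT, 41083 in KO), 88 to 90 Mb and 64 to 65 Mb. The other covered the end of the long arm of chromosome X from 155 Mb, with F8, the gene of coagulation factor VIII, and TMLHE (57 peaks in WT, 10 in KO). With equally many peaks from each list, 46898, fewer KO bases were found in 27.6% of windows.

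Adjacent windows moved together over several megabases. On chromosome 21 from 18 to 26 Mb, with CHODL, TMPRSS15, NCAM2 and APP, the gene of the amyloid precursor protein, 82 WT and 1315 KO peaks were called. On chromosome 19 from 19 to 25 Mb there were 232 and 1341 peaks, and 37 of the 62 protein-coding genes there are zinc finger genes. Chromosome 7 from 61 to 65 Mb had 300 and 877 peaks, and 2 further stretches on chromosome 19 began at 51 and 56 Mb. In the opposite direction, chromosome 3 from 149 to 178 Mb had 401 WT and 163 KO peaks over 29 windows in a row, each with fewer KO bases, and HLTF lies in the first of these windows. Chromosome 10 from its start to 27 Mb had 451 and 208 peaks over 27 windows. Beyond 76 Mb on chromosome X, a bound set after seeing the data, 74 of 80 windows had fewer KO bases, against 14 of 73 windows below it. In 1000 shuffles of the windows of all chromosomes together the longest run of such windows was 6. Such shuffles keep no likeness between neighbouring windows and no difference between chromosomes.

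**Figure D3:**
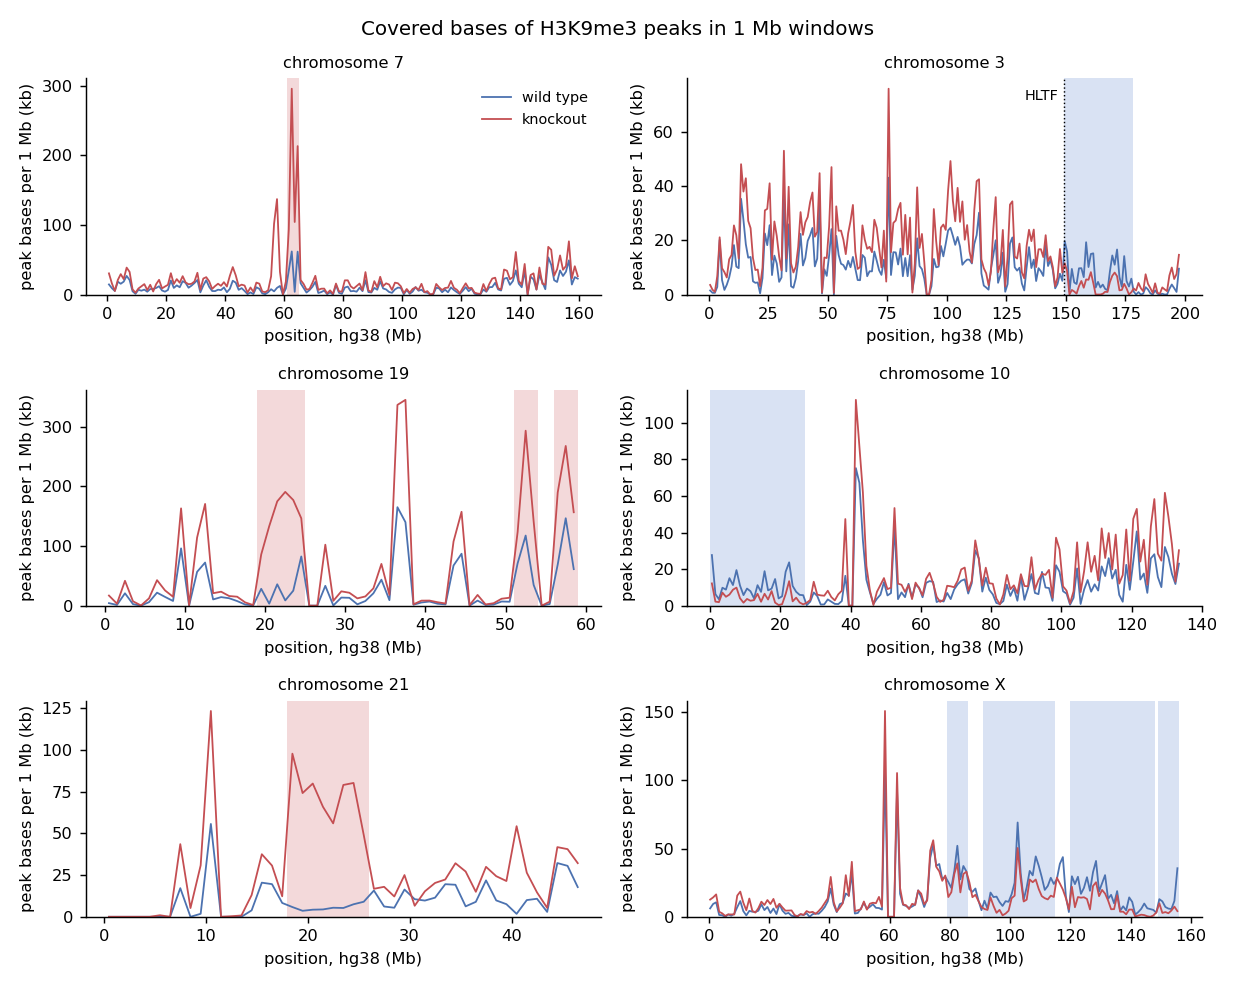
Covered bases of H3K9me3 peaks (kb) in windows of 1 Mb along chromosomes 7, 19, 21, 3, 10 and X (position in Mb, hg38), in WT (blue) and KO (red). Pink bands mark stretches of gain and blue bands stretches of loss in KO. The dotted line marks HLTF, which lies in the first window of the loss from 149 to 178 Mb on chromosome 3.

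At the level of genes, 6501 had a peak in both lists, 2197 in KO alone and 563 in WT alone. In lists of 46898 peaks each these were 1401 in KO alone and 1217 in WT alone. Among the genes of both lists, 5119 had more peak bases in KO and 1379 had fewer. The genes with the most KO-only peaks clustered on chromosomes 21, 14 and 19. DSCAM (ENSG00000171587), a neuronal cell adhesion gene on chromosome 21 from 40010999 to 40847139, had 2 WT and 111 KO peaks. NCAM2 and CHODL had 1 and 4 WT peaks and 68 and 55 KO peaks, and TMPRSS15, the gene of enteropeptidase, had 2 and 43. On chromosome 14, GPHN, which encodes the synaptic scaffold gephyrin, had 44 and 74 peaks, and the noncoding genes AL390334.1 and LINC02307 had 5 and 46 and 6 and 46. On chromosome 19, ZNF98 had 2 and 44 peaks and the noncoding AC008554.1 had 0 and 43. Of the 10 genes with the most WT-only peaks, 6 lay in the stretches of loss. TMLHE, an enzyme gene of carnitine synthesis on chromosome X, had 22 WT and 4 KO peaks. IL1RAPL2 on the same chromosome had 31 and 21. DNAJC1 and ZMYND11 on chromosome 10 had 21 and 5 and 15 and 6, and RSRC1 on chromosome 3 had 13 and 3. The noncoding AL390957.1 on chromosome 1 had 22 and 16 peaks.

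Some long genes had many peaks of both kinds. PCDH9, a protocadherin gene on chromosome 13 (66302834 to 67229818), had 114 WT and 136 KO peaks, with 23 WT-only and 43 KO-only. GPC5, which encodes a glypican, had 103 and 90 peaks, CNTNAP2 had 70 and 80, and RNF219-AS1 had 52 and 64. Peak bases over PCDH9 and CNTNAP2 were higher in KO by 6654 and 10746, but in lists of equal length KO minus WT was -40283 and -5534. Over GPC5 and AL390957.1 KO minus WT was -9719 and -1525 bases, and 3425 and 2856 bases among peaks past the common q, a looser cut for KO.

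Zinc finger genes of the C2H2 class, many of which encode KRAB repressors and whose 3' exons are known targets of H3K9me3, were the most marked of the 16 gene lists. Of 558 such genes, 322 had a WT peak (57.7%, 53.6 to 61.7) and 358 had a KO peak (64.2%, 60.1 to 68.0), above all 10000 random lists of the same gene lengths, whose medians were 15.8% and 18.5%. A KO peak alone was found at 42 and a WT peak alone at 6, and 343 had more peak bases in KO and 21 fewer. Covered bases at these genes were 1919467 in WT and 3577464 in KO, a ratio of 1.86, against 1.49 for all protein-coding genes. ZNF675 had 9 WT and 45 KO peaks, ZNF420 28 and 43, ZNF98 2 and 44, and ZNF717 26 peaks in each with 23131 and 44565 bases. Split by chromosome after seeing the data, the ratio of bases was 2.21 for the 260 zinc finger genes of chromosome 19 and 2.08 for the other 1191 genes there. On the remaining chromosomes it was 1.51 for 298 zinc finger genes and 1.42 for the rest.

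**Figure D4:**
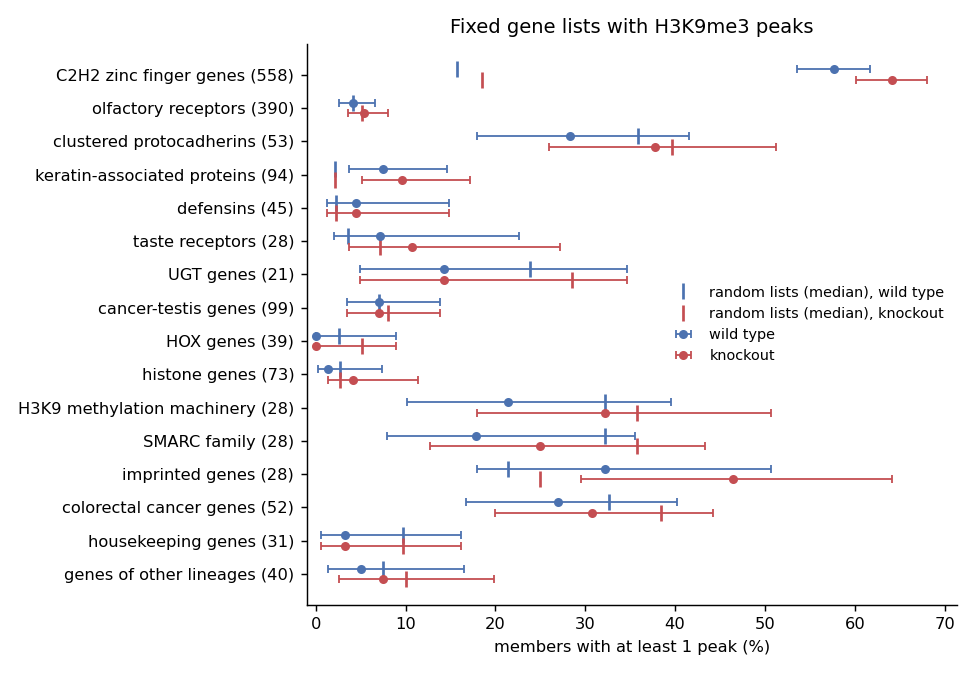
Share of the members of 16 gene lists (number of members in brackets) with at least 1 H3K9me3 peak, in WT (blue) and KO (red), with Wilson 95% intervals as bars and the median of random lists matched on gene length as upright ticks. C2H2 zinc finger genes stand at 57.7% and 64.2%, and HOX genes at 0% in both.

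Clustered protocadherin genes did not stand apart from random lists by assigned gene. Of 53, 15 had a WT peak and 20 a KO peak, at percentiles 8.91 and 33.9, and their mean gain of 316 bases lay at percentile 43.3. By overlap with gene bodies, 27 genes had more KO bases and 0 had fewer, and the mean gain of 3601 bases lay above all random lists, but these genes share their 3' exons, so the same peaks count for many of them. PCDHGA1 had 1 WT and 4 KO peaks, and PCDHGA6, PCDHGB5 and PCDHGA11 1 WT and 4, 3 and 2 KO peaks. Imprinted genes had a peak at 9 of 28 in WT and 13 in KO, at percentile 91.8 and 99.9 of the random lists, but among peaks at or above the median fold of both lists the shares were 21.4% and 25.0%, and in lists of 46898 peaks 32.1% and 35.7%. Among them ZIM2 had 1 and 17 peaks, PEG3 1 and 7, and ZNF331 2 and 9, all on chromosome 19 in the stretches of gain, and PLAGL1 on chromosome 6 had 9 and 15. In lists of equal length at the stricter threshold the difference of bases at ZNF331, PEG3 and PLAGL1 was negative.

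Genes of H3K9 methylation itself had a peak at 6 of 28 in WT and 9 in KO, and all 9 had more KO bases, but in lists of 46898 peaks the number was 6 in both. ATF7IP, a partner of the methyltransferase SETDB1, had 16 and 28 peaks, EHMT1, which encodes an H3K9 methyltransferase, 0 and 4, TASOR of the HUSH complex 1 and 4, and MORC2 1 and 3. The SMARC family had 5 and 7 of 28, with ZRANB3 at 14 and 19 peaks, SHPRH at 2 in each, SMARCAL1 at 0 and 1 and CHD7 at 1 in each. Of 52 colorectal cancer genes, 14 and 16 had a peak, with MGMT, a DNA repair gene, at 19 peaks in each and 17558 and 28507 bases, RSPO2 at 3 and 9, BRAF at 5 and 6 and CTNNB1 at 3 and 4. These lists lay between percentiles 3.96 and 35.3 of the random lists in both genotypes.

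Most other gene families were marked at few members. Olfactory receptors had a peak at 16 and 21 of 390. OR10H4 had 4 and 2 peaks but 3204 and 4879 bases, and OR2F1 had 4 and 1 peaks and 1595 and 779 bases. Keratin-associated proteins had 7 and 9 of 94, above percentile 99.9 in both genotypes, with KRTAP4-6 at 0 and 5 peaks and KRTAP10-4 at 8 and 12. KRTAP19-2 had 1 peak in each, with 2670 bases in WT and 1151 in KO. Defensins had 2 and 2 of 45, with DEFB125 at 6 and 7 peaks, and taste receptors 2 and 3 of 28, with TAS2R39 at 0 and 1. UGT genes, with UGT3A1 at 4 and 2 peaks but 1839 and 3030 bases, had 3 and 3 of 21 by assigned gene. By overlap with gene bodies 10 and 10 had a peak (47.6%, percentiles 98.8 and 96.0). Members such as UGT1A8 and UGT1A10 overlap and end at the same position, so the same peak can count for several of them. Cancer-testis genes had 7 and 7 of 99, with SYCP1 at 5 and 9 peaks and DAZL at 2 and 6. Histone genes had 1 and 3 of 73, the KO peaks at H3C3 and H2BC3 being absent from the WT list. Genes of other lineages had 2 and 3 of 40, with PTPRC at 2 peaks in each, and housekeeping genes 1 and 1 of 31, at PGK1. None of 39 HOX genes had a peak in either list, which allows a share of up to 8.97% by the Wilson interval.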

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

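The tests of the share of KO-only peaks on the constant background were written down before their result was seen. The comparisons with shared peaks and with each region's own level, which changed how those tests are read below, were added later. The other tests below were chosen after the patterns were seen. Unplaced, unlocalized or alternate sequences, left out of the overlap, chromosome, window and segment comparisons, held 424 WT and 572 KO peaks. Their ratio was 1.35 (1.19 to 1.53) for peaks and 2.11 for covered bases, with a mean width 1.56 times as large in KO.

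The longer KO list was set against a lower detection limit in KO, and the q-values show that such a difference in sensitivity exists. Among peaks of fold 6 and above, the ratio of KO to WT peaks was still 1.54 (1.43 to 1.66), which argues against the detection limit as the whole cause, while the ratio of 1.08 at the pooled median fold leaves room for it at weaker peaks. Stronger immunoprecipitation in the KO libraries cannot be told apart from a wider spread of the mark after loss of SMARCA3, because both would act on most of the genome. The ratio outside the gained and lost stretches was 1.39 (1.37 to 1.40), as either would give, but on chromosome X it was 0.999 (0.932 to 1.07) there and 0.793 with the stretches, so neither alone accounts for that chromosome, and 1 list per genotype keeps the question open for the others.

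Dense KO peaks on chromosomes 7, 19 and 21 were not removed by taking 27177 top peaks from each list. The stretches then held 726 WT and 1813 KO peaks, a ratio of 2.497 (2.29 to 2.72). They had been chosen for an excess of KO bases in these same lists, which favours a ratio above 1. The test therefore does not decide about the detection limit. On chromosome 21 the dense peaks were weak, with 26 WT and 159 KO peaks from fold 4 but 4 and 4 from fold 5. A gain of copies in the KO cells would raise the local input and move peaks off the constant background. KO-only peaks lay on that background more often inside the stretches than outside, by 39.2 percentage points on chromosome 21 (37.3 to 40.8), 24.1 on chromosome 7 (20.6 to 27.4) and 8.93 on chromosome 19 (6.65 to 11.2), and at shared peaks the share changed from WT to KO by 40.5 (20.9 to 56.0), -3.71 (-9.92 to 2.32) and -8.08 (-13.2 to -2.90), beside -3.59 (-4.35 to -2.82) outside the stretches. The rise at shared peaks of chromosome 21, from 39.1% of 46 WT to 79.6% of 49 KO peaks, does not decide about a copy gain. WT-only peaks of that stretch stood at 91.7%, so its WT shared peaks were not typical of the region. Under the rule written beforehand, a higher share of KO-only peaks inside the stretches, beyond its interval, argued against a copy gain. That rule was met on chromosomes 7, 19 and 21. Its outcome is not kept here, because the test of KO-only peaks took no account of each region's own level. On chromosome 7 WT shared peaks stood at 87.7% and 24 WT-only peaks at 87.5%. In the 3 stretches of chromosome 19 WT shared peaks stood at 73.6%, 53.7% and 40.4% (53.0% pooled, 53.5% outside). KO-only peaks there stood at 72.8%, 45.1% and 33.7% against 50.9% outside, above it in the first stretch alone. The few WT-only peaks there (16, 14 and 17) stood at 62.5%, 35.7% and 29.4% against 65.3% outside, below KO-only peaks in each stretch. The changes at shared peaks on chromosomes 7 and 19 were not shown to differ from that outside, so there a copy gain and a local gain of the mark cannot be told apart, and a local spread of H3K9me3 may remain as a hypothesis, untested without replicates, beside a copy change in the ChIP cells that the input cells lacked.

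Long stretches with fewer KO peaks on chromosomes 3, 10 and X ran over up to 29 windows, beyond the longest of 6 in 1000 shuffles, so chance does not account for them if windows are taken as exchangeable. A loss of copies in the KO cells would lower the local input, and at the shared peaks of these stretches the share on the constant background went from 55.5% in WT to 68.7% in KO, by 13.1 percentage points (9.26 to 16.9), while outside all stretches it changed by -3.59. A copy loss would give such a rise, but the rise is not particular to lost stretches, since it was 40.5 in the gained stretch of chromosome 21, and the lost stretch of chromosome X from 79 to 86 Mb showed none (-1.28, -10.2 to 7.64). In the stretches on chromosomes 1, 4 and 13 the change was 5.46 (-1.78 to 12.6), so copy loss and a loss of the mark cannot be told apart there. Copy loss stays a hypothesis found and tested on the same data, and a loss of H3K9me3 after the knockout remains untested for all of them.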

How the results depend on the processing

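No paired analysis was possible because the lists hold no value per replicate, and for the same reason the planned fits per region, with the replicate block, other normalization, no filter on low values or each replicate left out, were not run. The share of zinc finger genes with a KO peak stayed above all random lists with unmatched lists and with all genes as background, and the promoter difference moved past its interval only in equal lists of 46898 peaks (0.716 percentage points). Depth per library is unknown, and the detection limit differs between the lists. The alternatives at fold 5, fold 6 and the common q, the one without the long loss stretches and the all-gene background were chosen after seeing the data. The cause of the changes below was not tested, apart from what follows from keeping fewer or wider peaks or from the looser cut that a common q makes in KO. The ratio of KO to WT peaks stayed above 1 throughout, at 1.08 from the pooled median fold, 1.36 and 1.298 with peaks merged within 1 and 5 kb, 1.54 from 500 bp of width, 1.301 from fold 5, 1.54 from fold 6, 2.03 at the common q and 1.45 without the long loss stretches.

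Shared WT and KO peaks were 40.5% and 29.1% with 50% reciprocal overlap, 88.4% and 63.6% within 1 kb, 64.0% and 52.5% from the pooled median fold, 62.2% and 54.7% in equal lists of 27177 peaks, 65.9% and 56.1% in equal lists of 46898, 81.8% and 56.7% merged within 1 kb, 83.4% and 62.6% merged within 5 kb, 83.0% and 49.6% from 500 bp, and 82.7% and 38.3% at the common q. In the order of pooled median fold, equal lists of 27177 and equal lists of 46898, the ratio of bases was 2.24, 2.17 and 2.04 on chromosome 19, 2.37, 2.23 and 2.502 on chromosome 21, 0.735, 0.708 and 0.709 on chromosome X, and 0.952, 0.924 and 0.833 on chromosome 13, which turned from above to below 1. At the common q it was 3.10 on chromosome 19, 3.12 on chromosome 21 and 1.09 on chromosome X, which turned. A common q admits weaker peaks in KO, since a peak near fold 4 had a q of 8.9e-07 in WT and 3.1e-09 in KO. At a common fold the ratio of peaks on chromosome X was 0.584 from fold 4 and 0.682 from fold 6. By number of peaks it was 2.08, 3.52 and 0.793 on chromosomes 19, 21 and X. Windows with fewer KO bases were 23.2%, 25.7% and 27.6% in the same order, 7.44% at the common q and 16.3% by number of peaks.

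Genes with a peak in both lists were 4282 in equal lists of 27177 and 4179 at the common q. Genes with a KO peak alone were 1354 and 1401 in the shorter and longer equal lists. Genes with a WT peak alone were 903 from the pooled median fold, 983 and 1217 in the equal lists and 315 at the common q. Zinc finger genes with a peak were 50.4% in WT and 56.5% in KO both from the pooled median fold and in equal lists of 27177.

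Of the 69 named genes, 10 turned direction in peak bases from the pooled median fold, 12 and 10 in the shorter and longer equal lists and 6 at the common q. From the pooled median fold, KO minus WT became -11564 at PCDH9, -804 at OR6B1, -282 at DEFB128, -457 at TAS2R41, -723 at SYCP1, -1481 at TEX11, -2188 at PLAGL1, -306 at PEG3, -824 at CTNNB1 and -339 at CD4. In equal lists of 27177 it was -13959 at PCDH9, -1210 at CNTNAP2, -804 at OR6B1, -282 at DEFB128, -457 at TAS2R41, -723 at SYCP1, -1848 at TEX11, -395 at ZNF331, -2188 at PLAGL1, -306 at PEG3, -824 at CTNNB1 and -339 at CD4. In equal lists of 46898 it was -40283 at PCDH9, -5534 at CNTNAP2, -1392 at OR6B1, -118 at PCDHGA6, -238 at KRTAP10-4, -167 at UGT3A1, -21 at SYCP1, -1109 at TEX11, -913 at PLAGL1 and -339 at CD4. At the common q it was 3425 at GPC5, 2856 at AL390957.1, 268 at OR2F1, 671 at UGT1A8, -404 at CTNNB1 and -339 at CD4. The number of members with a peak, KO minus WT, turned to -1 for taste receptors and histone genes and -2 for the SMARC family from the pooled median fold and in equal lists of 27177, to -1 for olfactory receptors in equal lists of 27177, and to -1 for genes of other lineages in equal lists of 46898. In lists of 46898 peaks KO minus WT fell from 36 members to 20 for zinc finger genes, from 5 to 1 for olfactory receptors, from 5 to 2 for clustered protocadherins, from 4 to 1 for imprinted genes, from 3 to 0 for genes of H3K9 methylation and from 2 to 0 for the SMARC family. From the pooled median fold the share of genes of H3K9 methylation fell in both genotypes, from 21.4% to 10.7% in WT and from 32.1% to 17.9% in KO, and that of the SMARC family stayed at 17.9% in WT and fell from 25.0% to 10.7% in KO.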

Other observations

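All tests in this part were chosen after seeing the data. Splitting each chromosome into segments of constant KO share of peaks gave 16 segment ends on 9 chromosomes and showed regions not described so far. On chromosome 14 a segment from 39.6 to 44.7 Mb, which takes in LINC02307, held 43 WT and 297 KO peaks, and the part of chromosome 15 below 34.0 Mb held 1 WT and 72 KO peaks. The gain on chromosome 21 ran from 17994227 to 25360229 with 70 WT and 1307 KO peaks, and the segment next to it on the lower side, from 10.7 to 17.9 Mb, held 157 and 131. On chromosome X the only end lay beside the centromere at 58.3 Mb, with 588 WT and 769 KO peaks before it and 2879 and 1980 after it. On chromosome 10 the loss reached 28.5 Mb, with 454 and 210 peaks.

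On chromosome 3 the fewer KO peaks began near the targeted gene. The segment end fell between peaks at 149024945 and 149389794, a gap that contains HLTF, with an interval from 148786504 to 149821567, and the KO share of peaks was 59.4% before it and 28.7% after it, up to 177.4 Mb. Of 19974 protein-coding genes, 14, or 0.0701%, overlapped a gap that holds any of the 16 ends, HLTF among them, a measure that favours wide gaps such as this one. HLTF lay 121 kb from the middle of its gap. By distance, 31 genes (0.155%) lay as near an end as HLTF, and on chromosome 3 it was 4 of 1066 (0.375%). At shared peaks of the lost stretch the share on the constant background was higher in KO by 14.7 percentage points (2.80 to 26.0), though such a rise is not particular to lost stretches. A candidate explanation is a chromosome break at or near the targeted gene, with loss of a copy of the part beyond it in the KO cells. It was found and tested on the same data, the labels do not state how the knockout was made, and a single pair of lists does not show whether all KO cultures carry it. The losses on chromosomes 10 and X do not lie at the targeted gene.

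A gain aimed at zinc finger genes was set against a gain of the whole of chromosome 19. There the ratio of KO to WT peak bases at zinc finger genes was 1.06 times that at the other protein-coding genes (0.850 to 1.29 over 2000 resamples of genes), and on the other chromosomes 1.06 times (0.987 to 1.16). These values leave open whether zinc finger genes gained more than their neighbours, many of which lie between them.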
